A study of Mus musculus with 6 samples.

How the data were processed

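Poly(A) RNA of 6 cultures of TgSpi1 erythroleukaemic cells, 3 untreated and 3 given doxycycline for 48 h to induce an shRNA against Spi1, was sequenced after Illumina TruSeq RNA v2 library preparation, per the labels' protocols. This kit does not mark the strand. The authors deposited 1 table of raw read counts per gene symbol, with 25628 symbols and a column for each of the 6 libraries. The submitters' processing notes list bcl2fastq 2.17.1.14, STAR, DESeq2 and the mouse builds mm10 and GRCm38, without saying what each was used for. The counter, its annotation, its strand setting and its treatment of reads that match several genes are not given in the sources used here, so values of overlapping genes and of near-identical copies are uncertain. The smallest value in every column of the deposited counts was 1. A mean of 6549 genes per library had that value, 1964 had a value of 2 and 929 a value of 3, and no 0 occurred, so that 1 appears to have been added to each count. The test used the values as deposited, and taking 1 off each value was an alternative chosen after the data were examined. Each column was matched to its sample by its name, and every sample had a group from its title.

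The total count per library was 88377532, 78926663 and 98103600 in untreated replicates 1, 2 and 3 and 91277560, 95923009 and 101276319 in doxycycline replicates 1, 2 and 3. At this depth counting error was small beside the spread between cultures for a gene of 5 CPM or more. The 10 most abundant symbols took between 3.67% and 4.83% of the counts. No pair of libraries agreed within sampling noise: the chi-square per gene was between 158 and 601 over the pairs, so none was a copy of another. This does not show that the cultures were separate. Each was counted as a replicate because the labels call them biological replicates.

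The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM factors, two-sided, on the 14158 genes that filterByExpr kept, with the group as the only term. Benjamini-Hochberg adjusted p under 0.05 was the threshold. A log2 fold change is doxycycline over untreated, its SE is the size of the fold change divided by the square root of F, and CPM are edgeR's cpm values on TMM-scaled library sizes, given as mean ± SD. The same fit with the replicate number as a block was an alternative. The numbers were taken to pair the samples because libraries with the same number deviated together from their group means across genes. Their correlations were 0.77, 0.74 and 0.72 for numbers 1, 2 and 3. Those of unlike numbers were between -0.59 and -0.09. The latter are no separate support, since deviations from a group mean cancel out and make them negative on balance. The labels do not say what a number stands for. The block left 2 residual degrees of freedom in place of 4, lowered the common biological coefficient of variation from 28.6% to 11.3%, and 6127 genes differed between the numbers. Block values are given beside a result where they change its call or move a count by more than 1.5 times. Where the block is not named, passed, rose and fell refer to the fit without it.

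Gene lists were fixed before the data were examined, as were the test, the alternatives not listed below as added and the rule for named genes. There were 28 lists: globins, red cell membrane and surface, heme synthesis and iron handling, erythroid transcription factors and cofactors, stem and progenitor factors, myeloid genes bound or activated by PU.1, neutrophil granule, monocyte and macrophage, B cell, T and NK cell, megakaryocyte and platelet, mast cell and basophil, and stromal and endothelial markers, the ETS family, polycomb complexes, histone deacetylases and corepressors, DNA replication and G1/S, G2/M and mitosis, CDK inhibitors and pocket proteins, the BCL2 family, autophagy and organelle clearance, EPO and KIT signalling, type I interferon response, integrated stress response, mitochondrially encoded mRNAs, p53 targets, cholesterol synthesis and replication-dependent histones. They were drawn up from general knowledge and some share members. Older symbols of 18 members were matched through a RefSeq table. Lists with at least 3 tested members, 27 of the 28, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. Camera compares a list with all other genes tested, and fry asks whether its members move, on balance, one way. With an estimated correlation camera also rests on the residual degrees of freedom, 4 without the block and 2 with it. This lowers its power, so a list that fails it is not shown to be unmoved, nor its genes to be correlated.

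Named genes were Spi1, the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap of the groups, clone and model names passed over, and up to 3 members of each list with the smallest adjusted p under 0.05, or, where none passed, the 2 with the highest mean CPM. Genes that were picked apart from this rule, after their values were seen, are said to be so; this also holds for the further list members given with block values. Gene positions, transcript lengths and GC content came from GENCODE M21 (GRCm38), which held 24876 of the symbols.

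The steps were tested on simulated counts with 200 genes changed by known folds (Python 3.11.15 and matplotlib 3.10.9 drew the figures). The changed genes all had a mean of at least 5 CPM, so the shares recovered do not cover genes of lower CPM. On counts drawn for the doxycycline against untreated comparison over 13996 genes, with the fitted differences between replicate numbers, the fit without the block recovered 25% of 2-fold and 90% of 4-fold changes with 0% false calls, and the fit with the block 99% and 100% with 4.8% false calls. A gene that did not pass without the block is therefore not shown to be unchanged. The length and GC correction brought a slope of 0.30 over transcript length, put into all the doxycycline libraries, to 0.01 over 13886 genes. Alternatives were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma voom, a threshold of 0.01, the block, and each library left out. Added after the data were examined were the block together with DESeq2, with the other scaling factors, with 1 taken off each value, with a correction for transcript length and GC content (a spline trend per library in the offsets) and without each replicate number, and the unblocked fit without both replicate 3 libraries.

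For chromosomes, log2 CPM with a prior count of 2 was used. The replicate 3 library of each group was set against the mean of its replicates 1 and 2, the 2 differences were averaged, and medians were taken over genes of at least 5 mean CPM per chromosome and in windows of 20 neighbouring genes.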

Results

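The data were RNA-seq gene counts from mouse TgSpi1 erythroleukaemic cells, leukaemic erythroid blasts of bone marrow origin that overexpress the transcription factor PU.1, encoded by Spi1. The cells were grown with erythropoietin. They carried an shRNA against Spi1 that doxycycline switches on, and were either given doxycycline for 48 h or left untreated. There were 3 libraries per group, numbered 1 to 3 in each, which the labels call biological replicates. Total counts lay between 78926663 in untreated replicate 2 and 101276319 in doxycycline replicate 3, over 25628 gene symbols. The comparison addressed which transcripts depend on a high Spi1 level in these cells, and the series title places it in a study of gene repression by SPI1 together with HDAC1 and the polycomb complex PRC2.

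Spi1 itself fell with doxycycline in every library. The gene (ENSMUSG00000002111.8, protein coding, chromosome 2 from 91082390 to 91115756 on the plus strand, GRCm38) stood at 366 ± 43.8 CPM in the untreated libraries (SD, n = 3) and at 75.8 ± 12 CPM with doxycycline (SD, n = 3). The log2 fold change was -2.27 (SE 0.17, edgeR adjusted p = 0.0030). Within the pairs of equal replicate number it was -2.29, -2.14 and -2.41. No untreated library was below 329.6 CPM and no doxycycline library above 84.8 CPM. The position is that of the annotated gene, and counts per symbol do not tell from which copy of Spi1 the reads came.

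**Figure D1:**
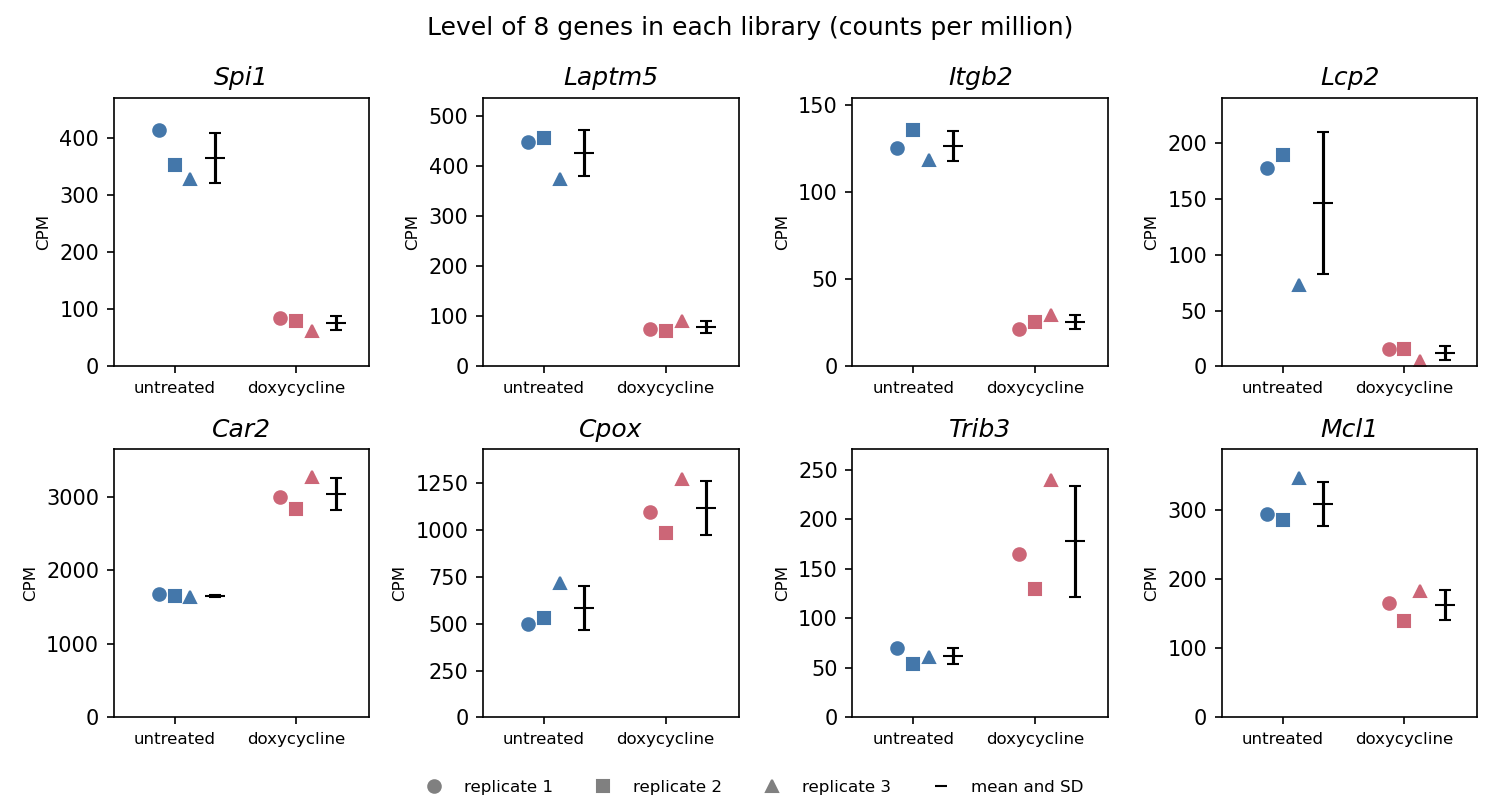
CPM (vertical axis, starting at 0) of 8 genes in the untreated and doxycycline libraries; each symbol is 1 library, its shape gives the replicate number, and the bars give the mean and SD of 3 libraries. Spi1, Laptm5, Itgb2, Lcp2 and Mcl1 were lower in each doxycycline library than in any untreated library, and Car2, Cpox and Trib3 were higher.

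The largest falls with doxycycline exceeded the largest rises. The falls among genes of at least 5 mean CPM were led by Rnase6, a myeloid ribonuclease (log2 fold change -5.24, SE 0.39), Plcb2, a phospholipase C of haematopoietic cells (-4.42, SE 0.50), Ccdc88b (-4.30, SE 0.48) and Tmem176b (-4.23, SE 0.64). They were followed by Sla, an adaptor that dampens antigen receptor signalling (-4.00, SE 0.29), Hcls1, a cortactin relative of haematopoietic cells (-3.83, SE 0.42), Lcp2, the adaptor SLP-76 (-3.60, SE 0.54), and Cst7, a cystatin of leukocytes (-3.58, SE 0.58). Lpcat2 and Atp8b5 both stood at -3.17 (SE 0.22 and 0.26). Lcp2 went from 146 ± 63.8 to 12.1 ± 5.96 CPM and Rnase6 from 10.01 ± 2.97 to 0.263 ± 0.0901 CPM (SD, n = 3 each). Adjusted p of these 10 genes lay between 0.0030 and 0.026.

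The largest rises were led by Pkhd1l1 (log2 fold change 2.51, SE 0.43), Tgm2, transglutaminase 2 (2.47, SE 0.33), Fads3 (2.26, SE 0.33), Igfbp5, a binding protein of insulin-like growth factors (2.21, SE 0.41), and Uros, an enzyme of heme synthesis (1.73, SE 0.27). Tmem56 (1.64, SE 0.18), Mycl, a relative of Myc (1.59, SE 0.31), Acot2 (1.58, SE 0.26), St3gal6 (1.57, SE 0.29) and Trib3, a pseudokinase induced by cell stress (1.52, SE 0.24), completed the 10. Tmem56 was the most abundant of these and went from 84.1 ± 12.5 to 262 ± 40.9 CPM (SD, n = 3 each). Adjusted p of the 10 lay between 0.010 and 0.046. Uros overlaps Bccip, Tgm2 overlaps Rprd1b, St3gal6 overlaps Dcbld2, Sla overlaps Tg, Lpcat2 overlaps Capns2 and Tmem176b overlaps Tmem176a. Of the list members named below, Cpox overlaps Gpr15, Elf1 overlaps Wbp4, Plek overlaps Cnrip1 and Atf5 overlaps Nup62 and Il4i1, among others. The library kit does not mark the strand. The split of reads between these partners, and between Acot2 and its near-identical relatives, is therefore uncertain.

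Of 14158 genes tested with edgeR's quasi-likelihood test, 59 were higher and 308 lower with doxycycline at an adjusted p under 0.05. At least a 2-fold change was seen for 38 of the higher and 261 of the lower genes. With the replicate number as a block, 1452 genes were higher and 2206 lower, of which 317 and 788 changed at least 2-fold. All 367 genes called without the block were called with it, in the same direction. The share of called genes that fell was 83.9% without the block, 60.3% with it, 68.4% by DESeq2 and 48.9% by DESeq2 with the block, where 1736 genes were higher and 1660 lower. Leaving out a single library kept 49, 43 and 215 of the 367 calls without untreated replicates 1, 2 and 3, and 38, 102 and 170 without doxycycline replicates 1, 2 and 3. The CPM of the groups did not overlap for 20.6% of the genes tested, where chance gives 10% if all 6 libraries are exchangeable, which the pairing by replicate number makes them not.

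**Figure D2:**
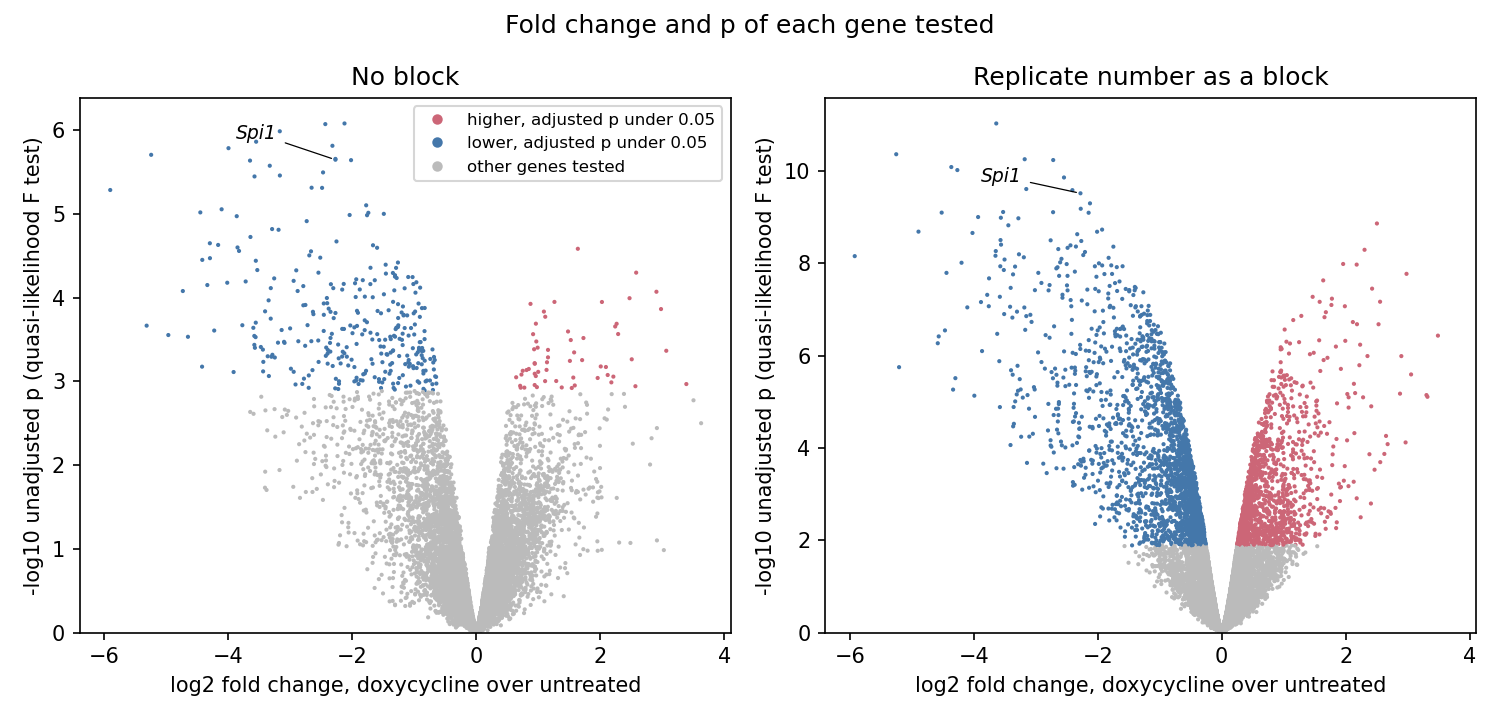
Log2 fold change of doxycycline over untreated libraries (horizontal axis) against the -log10 unadjusted p of the quasi-likelihood test (vertical axis) for the 14158 genes tested, without (left) and with (right) the replicate number as a block; each point is a gene. The coloured points have an adjusted p under 0.05: 59 higher and 308 lower on the left, 1452 and 2206 on the right.

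The myeloid genes that PU.1 binds or activates were lower as a group. Of 42 tested members of this list, 13 fell and 1 rose, and 27 fell and 2 rose adjusted over the list alone, with a median log2 fold change of -1.37. With the block 31 fell and 2 rose. Laptm5, a lysosomal membrane protein of blood cells, went from 427 ± 45.4 to 78.9 ± 11.2 CPM (log2 fold change -2.44, SE 0.16, adjusted p = 0.0030). Itgb2, the common beta chain of the leukocyte integrins, went from 126 ± 8.62 to 25.3 ± 4.04 CPM (-2.32, SE 0.17, adjusted p = 0.0030; SD, n = 3 each). Il1b, the inflammatory cytokine interleukin 1 beta, was the member that rose, from 0.893 ± 0.0347 to 5.35 ± 1.82 CPM (2.58, SE 0.31, adjusted p = 0.014). The list as a whole passed camera with a preset correlation (adjusted p = 1.25e-24) and fry (adjusted p = 0.011). It did not pass camera with an estimated correlation (adjusted p = 0.11, and 0.13 with the block). With the block that estimate was -0.0055, below the preset 0.01. Correlation among its genes therefore does not account for the miss with the block, where the test rested on 2 residual degrees of freedom.

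Other members of the ETS family, to which PU.1 belongs, fell too. Ets1 went from 31.8 ± 4.37 to 11.6 ± 1.18 CPM (log2 fold change -1.46, SE 0.17) and Elf1 from 142 ± 7.46 to 69.8 ± 4.11 CPM (-1.03, SE 0.12; SD, n = 3 each), both with an adjusted p of 0.014. These were the 2 of 17 tested members that passed (also 2 adjusted over the list alone), and none rose. With the block 8 fell, among them Fli1 (-1.17, SE 0.20) and Elf4 (-1.08, SE 0.095), which were picked after their values were seen. The list passed camera (adjusted p = 0.0024; adjusted p = 0.40 with an estimated correlation) and not fry (adjusted p = 0.075, and 0.025 with the block). Of 15 stem and progenitor factors, Meis1, a homeobox factor of progenitors and leukaemia, fell from 8.85 ± 2.08 to 2.33 ± 0.406 CPM (-1.92, SE 0.27, adjusted p = 0.018), 5 fell adjusted over the list alone, and with the block 7 fell and 1 rose. This list passed camera (adjusted p = 8.3e-04; adjusted p = 0.13 with an estimated correlation) and fry (adjusted p = 0.015).

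Genes of the red cell membrane and surface were among those that rose. Car2, the carbonic anhydrase of red cells, went from 1654 ± 14.4 to 3034 ± 216 CPM (log2 fold change 0.88, SE 0.12, adjusted p = 0.017). Aqp1, the water channel, went from 114 ± 19.8 to 218 ± 24.5 CPM (0.94, SE 0.17, adjusted p = 0.038), and Trim10, an erythroid TRIM protein, from 45.4 ± 8.10 to 88.3 ± 11.1 CPM (0.96, SE 0.18, adjusted p = 0.040; SD, n = 3 each). These 3 of 28 tested members passed and none fell, while 12 rose adjusted over the list alone, and 19 rose and 2 fell with the block. The risers with the block included Slc4a1, the anion exchanger band 3 (1.15), and Rhd (1.02), and the fallers included Slc2a1, a glucose transporter (-0.53), all named after their values were seen. The list passed camera (adjusted p = 4.9e-09; adjusted p = 0.13 with an estimated correlation), with a median of 0.70, and not fry (adjusted p = 0.058, and 0.025 with the block).

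Enzymes of heme synthesis were also among the genes that rose. Of 35 tested genes of heme synthesis and iron handling, Uros (19.9 ± 2.78 to 66.0 ± 24.1 CPM) and Cpox, coproporphyrinogen oxidase (582 ± 118 to 1118 ± 146 CPM, log2 fold change 0.94, SE 0.18, adjusted p = 0.045; SD, n = 3 each) rose, and none fell, also adjusted over the list alone. With the block 19 rose and 1 fell. Those 19 included the pathway enzymes Alas2 (0.34), Urod (0.48), Ppox (0.73) and Fech (0.54) beside Uros (1.68) and Cpox (0.95), whereas Alad had a log2 fold change of 0.09 (block adjusted p = 0.48). The transferrin receptor gene Tfrc rose with the block from 2101 to 3099 CPM (0.56). Ncoa4, which carries ferritin to breakdown, was the member that fell (-0.41). The list passed camera (adjusted p = 1.7e-05; adjusted p = 0.51 with an estimated correlation) and not fry (adjusted p = 0.27, and 0.045 with the block).

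The globins did not move together. Of 7 tested members Hbb-bh2, a minor beta-like globin, fell from 3.09 ± 1.56 to 0.226 ± 0.118 CPM (log2 fold change -3.77, SE 0.56, adjusted p = 0.022; SD, n = 3 each), also adjusted over the list alone. With the block Hba-a1 (0.40) and Hbq1b (1.34) rose and Hbb-bs (-0.37) and Hbb-bh2 fell. The near-identical adult copies share reads, and the list did not pass camera (adjusted p = 0.39). Of 23 erythroid transcription factors and cofactors none passed, 2 rose adjusted over the list alone, and 5 rose and 3 fell with the block. The 2 most abundant were Trim28 (487 ± 20.7 and 464 ± 27.7 CPM untreated and with doxycycline) and Ikzf1 (380 ± 42.2 and 425 ± 48.9 CPM; SD, n = 3 each). Gata1, the master factor of this lineage, picked apart from the rule, stood at 274 ± 16.8 and 268 ± 34.3 CPM (log2 fold change -0.03, SE 0.14, adjusted p = 0.95). The camera test gave an adjusted p of 0.30 for the list.

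Genes of the integrated stress response, the programme that ATF4 drives, were among those that rose. Trib3 went from 61.8 ± 7.85 to 178 ± 56.1 CPM and Atf5 from 69.8 ± 6.63 to 120 ± 15 CPM (log2 fold change 0.78, SE 0.15, adjusted p = 0.047; SD, n = 3 each). These were 2 of 29 tested members, none fell, and 11 rose adjusted over the list alone. With the block 20 rose and 1 fell, among the risers Ddit3, which encodes CHOP (0.81), Asns, asparagine synthetase (0.60), and the cystine transporter Slc7a11 (1.05), named after their values were seen. The faller was Psph, the last enzyme of serine synthesis (-1.35). The list passed camera (adjusted p = 6.1e-10; adjusted p = 0.40 with an estimated correlation) and not fry (adjusted p = 0.14, and 0.092 with the block). Trib3 was also the single riser among 29 tested genes of EPO and KIT signalling, of which none fell, also adjusted over the list alone. With the block 6 of these rose, Epor among them (0.43), and 6 fell. For this list the median was -0.10, the mean 0.08 and the camera direction up (adjusted p = 0.64).

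None of the 12 tested mitochondrially encoded mRNAs passed, and 2 rose adjusted over the list alone. With the block 5 rose and none fell. The cytochrome oxidase mRNA mt-Co1 stood at 4571 ± 505 CPM untreated and 6739 ± 450 CPM with doxycycline (log2 fold change 0.56, SE 0.14, adjusted p = 0.090, and 0.0067 with the block), and mt-Nd1 at 1908 ± 345 and 2170 ± 116 CPM (SD, n = 3 each). The list passed camera (adjusted p = 0.0016; adjusted p = 0.40 with an estimated correlation) and not fry (adjusted p = 0.12, and 0.23 with the block). With the block its median was 0.39 (adjusted p = 0.0080), and 0.20 after a correction for transcript length and GC content, where it did not pass (adjusted p = 0.12). Mitochondrial symbols took between 1.0% and 1.31% of the counts of untreated libraries and between 1.35% and 1.48% with doxycycline.

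Within the BCL2 family, which sets the threshold of apoptosis, the protective member Mcl1 fell from 309 ± 32.5 to 163 ± 22.1 CPM (log2 fold change -0.92, SE 0.15, adjusted p = 0.028). Bcl2l11, which encodes the killer protein BIM, rose from 13.5 ± 1.34 to 29.2 ± 7.24 CPM (1.11, SE 0.21, adjusted p = 0.043; SD, n = 3 each). The other 12 of 14 tested members did not pass, 2 rose and 3 fell adjusted over the list alone, and 3 rose and 4 fell with the block, among the fallers Bcl2l1, which encodes BCL-XL (-0.94). The camera test gave an adjusted p of 0.64. Of 20 tested p53 targets none passed, also adjusted over the list alone, and 3 rose and 2 fell with the block (camera adjusted p = 0.47). Rps27l stood at 172 ± 34.3 and 202 ± 42.9 CPM and Ccng1 at 148 ± 13.4 and 147 ± 25.2 CPM (SD, n = 3 each).

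Among the genes of the chromatin complexes that the series title names, few passed without the block. Of 37 tested histone deacetylases and corepressors Mbd2, a methyl-CpG binding subunit of NuRD, fell from 218 ± 9.50 to 115 ± 18.7 CPM (log2 fold change -0.92, SE 0.15, adjusted p = 0.027; SD, n = 3 each). Adjusted over the list alone 3 fell, and with the block 6 rose and 6 fell, including Hdac7 (-0.94). Hdac1, picked for the series title, stood at 79.3 ± 7.29 and 74.0 ± 5.89 CPM (-0.10, SE 0.14, adjusted p = 0.82). Of 27 tested polycomb genes none passed, also adjusted over the list alone, and with the block 6 rose and 2 fell. The PRC2 subunit genes, also picked for the title, had block log2 fold changes of 0.34 for Suz12 (adjusted p = 0.024), 0.23 for Ezh2 (adjusted p = 0.11) and 0.03 for Eed (adjusted p = 0.83). Rbbp7 stood at 702 ± 206 and 781 ± 269 CPM and Rbbp4 at 781 ± 130 and 658 ± 127 CPM (SD, n = 3 each). The camera tests gave adjusted p of 0.82 for the deacetylase list and 0.11 for the polycomb list.

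Few cell cycle genes passed the test without the block. Of 34 tested genes of G2/M and mitosis Racgap1, a GTPase activator of cytokinesis, fell from 242 ± 4.92 to 151 ± 9.04 CPM (log2 fold change -0.68, SE 0.12, adjusted p = 0.030), also adjusted over the list alone, and 1 rose and 6 fell with the block (camera adjusted p = 0.65). Of 38 tested genes of DNA replication and G1/S none passed, also adjusted over the list alone, and with the block 9 rose and 4 fell, with cyclin E1, Ccne1, at 0.75. Rrm1 stood at 770 ± 90.1 and 887 ± 142 CPM and Mcm5 at 512 ± 16.7 and 585 ± 46.7 CPM. This list missed the camera threshold without the block (adjusted p = 0.051) and passed it with the block (adjusted p = 0.041; adjusted p = 0.35 with an estimated correlation), as it did fry (adjusted p = 0.083 and 0.025). Of 12 tested CDK inhibitors and pocket proteins none passed, also adjusted over the list alone, and 3 rose and 2 fell with the block (camera adjusted p = 0.40). Cdkn2a stood at 263 ± 84.0 and 229 ± 63.9 CPM, and Rbl1 at 124 ± 8.42 and 149 ± 17.3 CPM (adjusted p = 0.45, and 0.049 with the block; SD, n = 3 each).

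Of 27 tested type I interferon response genes Oas2, an antiviral oligoadenylate synthetase, fell from 1.06 ± 0.109 to 0.207 ± 0.0691 CPM (log2 fold change -2.35, SE 0.33, adjusted p = 0.018; SD, n = 3 each). Adjusted over the list alone 6 fell and 1 rose, and with the block 12 fell and 2 rose. The list passed camera in the downward direction (adjusted p = 0.0071; adjusted p = 0.13 with an estimated correlation) and fry (adjusted p = 0.011).

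**Figure D3:**
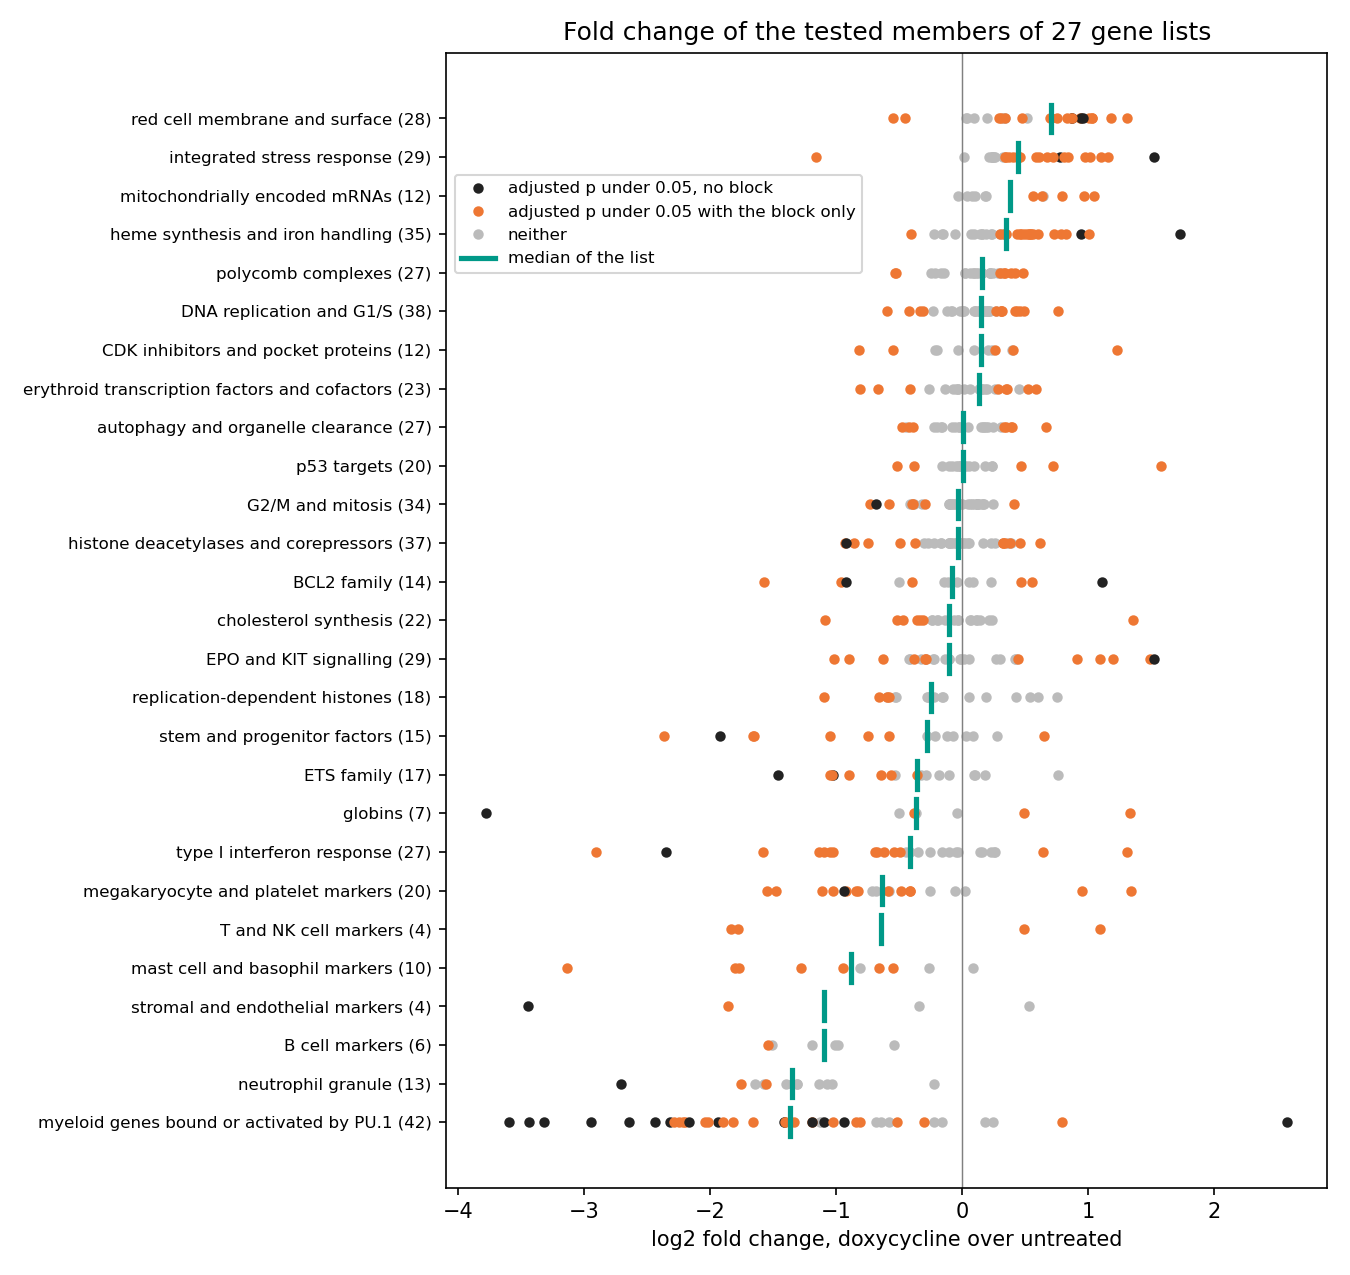
Log2 fold change of doxycycline over untreated libraries (horizontal axis) of the tested members of 27 gene lists, with the number tested in brackets; each point is a gene, black where its adjusted p was under 0.05 without the block, orange where it was so with the block alone, and the green bar is the list's median. The myeloid PU.1 list has the lowest median (-1.37) and the red cell membrane list the highest (0.70).

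Lists of other marrow lineages served to look for other cell types. Of 20 megakaryocyte and platelet markers Plek, pleckstrin, also a member of the myeloid list, fell from 624 ± 63.0 to 326 ± 56.8 CPM (log2 fold change -0.94, SE 0.16, adjusted p = 0.032). Adjusted over the list alone 6 fell and 1 rose, and with the block 12 fell, including Itga2b (-1.48) and Pf4 (-0.80), and 2 rose. Of 10 mast cell and basophil markers none passed, 2 fell adjusted over the list alone, and 7 fell with the block. Among the latter was Srgn, serglycin (234 ± 51.4 and 121 ± 29.1 CPM, adjusted p = 0.095, and 1.4e-04 with the block), while Gata2 stood at 330 ± 68.7 and 351 ± 84.7 CPM (SD, n = 3 each). Of 4 stromal and endothelial markers Vim, vimentin, fell from 4.32 ± 1.89 to 0.396 ± 0.253 CPM (-3.44, SE 0.57, adjusted p = 0.028), 2 fell adjusted over the list alone, and 2 fell with the block. These 3 lists passed camera, at adjusted p of 0.0014, 6.8e-04 and 0.018 (in the same order, adjusted p = 0.13, 0.13 and 0.20 with an estimated correlation), and fry, at 0.025, 0.044 and 0.044.

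Neutrophil granule transcripts differed between replicate numbers within each group. S100a9 stood at 0.0340, 14.9 and 3.34 CPM in untreated replicates 1, 2 and 3 and at 0.0110, 4.08 and 3.27 CPM in doxycycline replicates 1, 2 and 3, and S100a8, Camp, Ngp and Ltf were likewise highest in untreated replicate 2 and lowest in replicate 1 of both groups. Of 13 tested members Ms4a3 fell (0.463 ± 0.221 to 0.0700 ± 0.0288 CPM, log2 fold change -2.70, SE 0.53, adjusted p = 0.047; SD, n = 3 each), 2 fell adjusted over the list alone and 3 with the block (camera adjusted p = 0.085, and 0.053 with the block). With the block 11 fell adjusted over the list alone, and the log2 fold change was negative for all 13. For S100a9 it was -0.77, -1.87 and -0.03 in pairs 1, 2 and 3, and the value of pair 1 rests on deposited counts of 3 and 1. Of 2 tested monocyte and macrophage markers Ccr2 stood at 19.3 ± 3.02 and 18.2 ± 3.52 CPM and Apoe at 5.07 ± 1.97 and 3.55 ± 1.99 CPM (adjusted p = 0.71, and 0.041 with the block). Neither passed, also adjusted over the list alone.

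B and T cell transcripts were scarce. Of 6 B cell markers none passed, also adjusted over the list alone, and Cd74 (0.484 ± 0.248 and 0.165 ± 0.0587 CPM, adjusted p = 0.17, and 0.0060 with the block) fell with the block, whereas Ighm stood at 1.28 ± 1.82 and 0.447 ± 0.378 CPM. Of 4 T and NK cell markers none passed and 1 fell adjusted over the list alone. With the block 2 rose, including Lck (3.89 ± 1.04 and 5.46 ± 1.08 CPM, adjusted p = 0.48, and 0.029 with the block), and 2 fell, including Lat (1.92 ± 1.52 and 0.559 ± 0.349 CPM, adjusted p = 0.41, and 0.0021 with the block; SD, n = 3 each). The camera tests gave adjusted p of 0.22 for the B cell list and 0.64 for the T and NK cell list.

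Of 27 tested genes of autophagy and organelle clearance none passed, also adjusted over the list alone, and 5 rose and 3 fell with the block. Bnip3l stood at 224 ± 17 and 200 ± 34.9 CPM and Gabarapl1 at 184 ± 13.4 and 205 ± 21.1 CPM. Of 22 tested genes of cholesterol synthesis none passed, also adjusted over the list alone, and with the block 1 rose and 6 fell. Sqle stood at 295 ± 25.3 and 320 ± 35.5 CPM and Stard4 at 310 ± 6.98 and 242 ± 30.5 CPM (adjusted p = 0.26, and 0.018 with the block). Of 18 tested replication-dependent histone genes, measured here in poly(A) RNA only, none passed, also adjusted over the list alone, and 4 fell with the block. H1f0, which counts among the 4 and is, from general knowledge, expressed apart from replication, stood at 217 ± 96.7 and 102 ± 41.4 CPM (adjusted p = 0.23, and 7.9e-05 with the block) and H1f2 at 58.8 ± 31.2 and 39.5 ± 22.2 CPM (adjusted p = 0.67, and 0.0010 with the block; SD, n = 3 each). The camera tests gave adjusted p of 0.47, 0.41 and 0.64 for these 3 lists.

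Across the 27 lists with a set test, 11 passed camera with the preset correlation without the block and 12 with it, and 6 and 10 passed fry. With an estimated correlation 0 passed in either fit, where that test rested on 4 and 2 residual degrees of freedom. The libraries numbered 3 of both groups stood apart from those numbered 1 and 2 over chromosomes X, 2, 13 and 17. The median log2 ratio of replicate 3 over the mean of replicates 1 and 2 was -0.79 on X, -0.31 on chromosome 2, -0.39 on chromosome 17 and 0.35 on chromosome 13. It lay between -0.02 and 0.05 on the other 16 chromosomes. On X the shift was -0.75 in the untreated and -0.80 in the doxycycline library, and the median log2 doxycycline over untreated ratio of a chromosome was at most 0.05 in size. Of the genes named above, Spi1, Plcb2, Cst7, Tgm2, Trib3, Il1b, Vim, Bcl2l11, Bcl2l1 and Rbl1 lie on chromosome 2, H1f2 (by its older symbol Hist1h1c) on chromosome 13, Trim10 on chromosome 17 and Elf4, Alas2, Rbbp7 and Gata1 on X, Gata1 in its part without a shift.

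**Figure D4:**
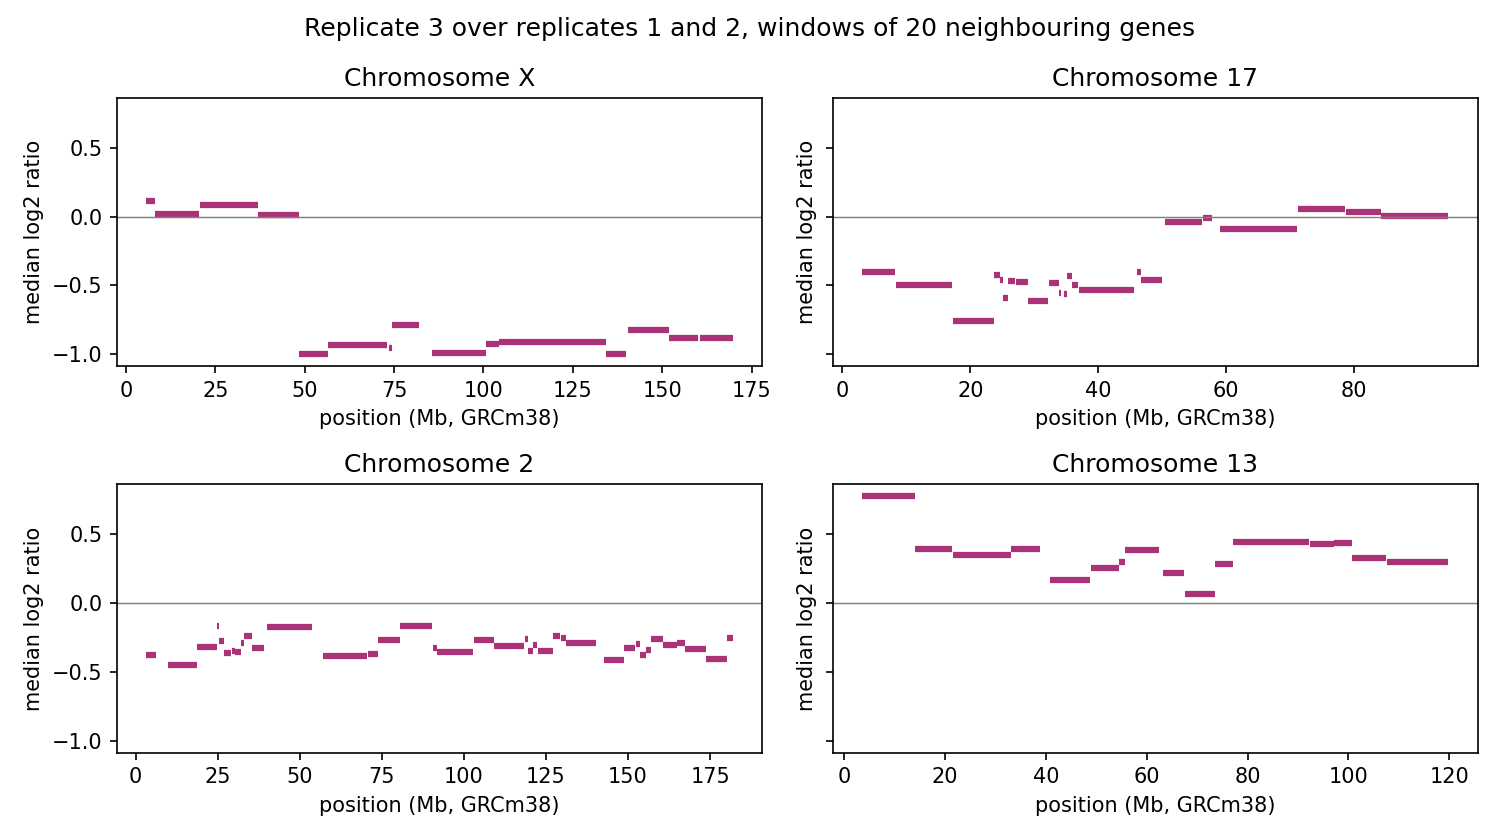
Median log2 ratio of the replicate 3 libraries over the mean of replicates 1 and 2, both groups averaged (vertical axis), in windows of 20 neighbouring genes along chromosomes X, 17, 2 and 13 (horizontal axis, Mb of GRCm38); each bar is a window from its first to its last gene. On X the 4 windows up to position 48341358 lie between 0.01 and 0.11 and the 11 from position 48411046 on between -1.0 and -0.79; on chromosome 17 the 17 windows up to 49992257 lie between -0.75 and -0.40.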

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

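Tests with the block and DESeq2, other scalings, 1 taken off each value, the length and GC correction or without a replicate number, and the unblocked fit without both replicate 3 libraries, were chosen after the data were examined. Spi1 kept its direction and its side of the threshold under every alternative run, with a log2 fold change between -2.36 and -2.14 over the left-out libraries and adjusted p up to 0.041. The 4 counts moved by less than 1.5 times under the 3 other scalings without the block, limma voom, no low count filter and 1 taken off each value, and with a mean of at least 1 CPM except for 25 genes at least 2-fold higher. At an adjusted p under 0.01, 0 genes were higher and 34 lower by edgeR; 2184 genes had an unadjusted p under 0.05. DESeq2 called 294 higher and 636 lower, 170 and 479 of them at least 2-fold. With the replicate block the counts, in the order higher, lower, at least 2-fold higher and at least 2-fold lower, were 1452, 2206, 317 and 788, with 1 taken off each value 1400, 2162, 326 and 769, with DESeq2 1736, 1660, 308 and 641, and with the length and GC correction 1895, 2294, 275 and 745. With the block and DESeq2 size factors they were 1622, 2118, 351 and 770, with library size alone 1350, 2100, 307 and 781, and with upper quartile factors 1833, 2001, 377 and 744. With the block they were 368, 880, 184 and 553 without replicate 1, 1310, 2119, 436 and 869 without replicate 2, and 2071, 2677, 330 and 843 without replicate 3. Leaving out 1 library, or both of replicate 3, without the block gave between 0 and 26 higher, 35 and 242 lower, 0 and 25 at least 2-fold higher and 35 and 234 at least 2-fold lower genes. The lowest came without untreated replicate 2 for the higher genes (1448 genes at an unadjusted p under 0.05) and without doxycycline replicate 1 for the lower. Fewer libraries leave fewer degrees of freedom; the cause of the other moves was not tested.

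Besides Spi1, 66 genes named by the rule were followed, of which 40 passed without the block. The block brought 10 of them past the threshold and changed no other call. Among the lists it brought DNA replication and G1/S past camera with the preset correlation and changed no other call of that test. By fry, 6 lists passed without the block and 10 with it. Leaving out 1 library took between 14 and 31 of these 40 below the threshold. Without both replicate 3 libraries 21 of the 40 lost their call and without the low count filter 7. With limma voom 4 did, with a mean of at least 1 CPM 2, with upper quartile factors 2 and with DESeq2 size factors 1. Lists also lost or gained camera calls at the preset correlation. Dropping the low count filter ended 1 and brought 4, and a mean of at least 1 CPM ended 1 and brought 1. Leaving out doxycycline replicate 2 ended 2 and brought 1, and the block without replicate 2 ended 1. The block with the length and GC correction ended 1 and brought 2, and the block without replicate 3 ended 1 and brought 4. Leaving out both replicate 3 libraries without the block ended 1 and brought 1. Some other settings brought calls and ended none. Reversals of direction were seen for genes and lists that had not passed, and their cause was not tested. Log2 fold changes that turned were 0.00059 for Trim28 (DESeq2), -0.017 for Rps27l (block with length and GC correction), and for Ccng1 0.0045 with DESeq2 size factors, 0.027 with upper quartile factors (0.016 with the block), 0.046 with DESeq2 and 0.042 with the block and DESeq2. With the block and without replicate 2, Ccr2 stood at 0.10, Ighm at 0.46 and Ccng1 at 0.0020, and Ccng1 at 0.019 without replicate 3. Without the block, leaving out libraries gave Ccr2 -0.29 to 0.070, Ighm -2.32 to 0.89, Gata2 -0.12 to 0.25, Rbbp7 -0.072 to 0.42, Cdkn2a -0.38 to 0.10 and Ccng1 -0.17 to 0.085. Lists whose camera direction turned had medians of 0.012 for the BCL2 family (mean of at least 1 CPM) and 0.016 (block without replicate 1), of -0.0011 for the deacetylases (block with length and GC correction) and 0.0073 (block without replicate 1), and of 0.055 for G2/M and mitosis (block without replicate 3). With libraries left out they were -0.11 to 0.038 for the deacetylases, -0.031 to 0.054 for G2/M and mitosis, -0.84 to -0.34 for T and NK cells, -0.14 to -0.014 for cholesterol synthesis and -0.43 to 0.095 for the histones. At 78926663 counts or more per library, counting error was small beside the spread between cultures for a gene of 5 CPM or more. For genes of lower CPM the part of depth was not tested. With the replicate number as a block the called genes went from 367 to 3658, so the spread between numbers limited the calls without it.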

Other observations

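Among further genes picked after their values were seen and not tested as a group, some that fell have roles in the actin cytoskeleton. Dock2, a Rac activator of leukocytes, went from 153 ± 45.8 to 23.03 ± 4.998 CPM with doxycycline (log2 fold change -2.74, SE 0.26, adjusted p = 0.0064), Arpc1b, an ARP2/3 subunit, from 290 ± 31.3 to 84.6 ± 12.2 CPM (-1.78, SE 0.16, adjusted p = 0.0058), and Rac2 from 600 ± 15.7 to 307 ± 24.5 CPM (-0.97, SE 0.12, adjusted p = 0.014). Was, the Wiskott-Aldrich gene, had a log2 fold change of -1.28 (SE 0.16, adjusted p = 0.014), Capg of -1.83 (SE 0.22, adjusted p = 0.014), Twf2 of -1.57 (SE 0.25, adjusted p = 0.025) and Coro1a, also a member of the myeloid list, of -2.64 (SE 0.48, adjusted p = 0.036). The broadly expressed Cfl1 (989 ± 45.2 to 832 ± 26.2 CPM, -0.25, adjusted p = 0.36) and Pfn1 (726 ± 81 to 616 ± 49.1 CPM, -0.24, adjusted p = 0.49; SD, n = 3 each) did not pass.

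Other genes picked in this way were Cat, catalase, which fell from 227 ± 34.1 to 56.0 ± 2.56 CPM (log2 fold change -2.02, SE 0.15, adjusted p = 0.0030), and Cbfb, the partner of the RUNX factors, which fell from 149 ± 17.1 to 58.9 ± 19.8 CPM (-1.34, SE 0.26, adjusted p = 0.044). Slc29a1, a nucleoside transporter, rose from 235 ± 38.1 to 452 ± 49.6 CPM (0.94, SE 0.17, adjusted p = 0.032), and Vegfa from 25.5 ± 3.31 to 49.0 ± 5.19 CPM (0.94, SE 0.16, adjusted p = 0.032). The mitochondrial ribosomal RNA mt-Rnr2 rose from 423 ± 13 to 742 ± 116 CPM (0.81, SE 0.15, adjusted p = 0.036; SD, n = 3 each). The amino acid genes Pycr1 (0.97), Slc1a4 (0.77) and Slc7a7 (1.05) passed with the block alone, at block adjusted p of 8.1e-04, 3.0e-04 and 1.0e-04. Of the genes in these paragraphs, Cat lies on chromosome 2, Slc29a1 and Vegfa on the shifted part of chromosome 17 and Was on the part of X without a shift.

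Of the tests that follow, the share of falls among genes changed at least 2-fold, the scalings and the correction with the block, the CPM lost beside S100a9, the run of X windows without a shift and the absence of a doxycycline control were chosen after the result was seen, and the patterns themselves were noticed in the same data. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and the real split, at 367 genes, was the 1 with the most. The highest other split called 229 and set untreated replicate 1 with doxycycline replicates 1 and 3 against the rest, and parted 1 pair of numbers where the real split parts 3. With the block, of the 4 splits that part all 3 pairs, again too few, 1 reached the real 3658 genes and the highest other called 0.

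The replicate 3 libraries of both groups were lower over part of chromosome X. A candidate explanation is that the culture numbered 3 had fewer copies of that part in some or all of its cells. A change of the whole chromosome is argued against: 73.3% of the 15 windows had a median below -0.2, and the first 4 windows in a row, with 80 genes, lay between 0.01 and 0.11. A change of a part stays open, as 150 genes under 5 CPM in the lower part, which the windows had left out, had a median log2 shift of -0.31 (quartiles -0.80 and 0.10), between the bounds of -0.5 and -0.2, beside 0.04 for 49 such genes before it. Transcript length and GC content are argued against, since the shift of X genes was -0.79 after their correction.

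More genes fell than rose with doxycycline, at 83.9% of called genes without the block and 60.3% with it, but not by DESeq2 with the block, at 48.9%. Without the block the lowest share under 3 other scalings was 81.9%, so the choice among these scalings did not make the pattern. They left the median log2 fold change of all genes between 0.0043 and 0.046. As 38 of the 59 higher and 261 of the 308 lower genes changed at least 2-fold, such moves could hardly alter the share. A larger scaling error therefore stays open. With the block the scaling factor cannot be told apart, as the lowest share was 52.2%, between the bounds of 50% and 55%. Neutrophil RNA in the untreated cultures as the source is argued against for 191 of the 308 genes that fell (62.0%). Each lost more CPM than S100a9 (a loss of 3.64 CPM), from general knowledge among the most abundant neutrophil transcripts. The size of the loss leaves this source open for the others. Of 13 neutrophil granule genes 11 fell with the block adjusted over that list alone, and 3 adjusted over all genes. The markers S100a8, S100a9, Camp, Ngp and Ltf fell in pair 2, S100a9 from 1171 to 397 counts. They hardly moved in pair 3, where S100a9 had 330 and 326. The median log2 ratio of untreated replicate 1 over 2 over the 308 was 0.028 (quartiles -0.17 and 0.23). For the 5 neutrophil markers this ratio lay between -8.79 and -7.69. Neutrophil RNA is thus argued against as the source for those of the 308 at or above the lower quartile. The calls without the block favour genes of small spread, and 0 of the 5 markers were among them. The ratio therefore decides nothing for genes called with the block alone. Length and GC bias cannot be told apart for all called genes with the block (54.8% fell after correction, bounds 50% and 55%), where the falls went from 2206 to 2294 and the rises from 1452 to 1895, so that the falls did not become fewer; it is argued against for those changed at least 2-fold, of which 73.0% fell after correction.

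With the block 20 of 29 integrated stress response genes and 5 of 12 mitochondrially encoded mRNAs rose (2 and 0 without it), and neither list passed camera with an estimated correlation (adjusted p = 0.40 for each, and 0.53 and 0.72 with the block). Doxycycline from general knowledge inhibits mitochondrial translation, so that the drug itself may have raised them apart from the loss of Spi1. The data hold 0 libraries given doxycycline without the shRNA, so the drug and the loss of Spi1 cannot be told apart here, nor for the other changes reported. Length and GC bias is argued against for the stress response list, whose median log2 fold change with the block was 0.43 before and 0.50 after correction. For the mitochondrial mRNAs the median went from 0.39 to 0.20, between the bounds of 0.1 and 0.3, and the camera adjusted p from 0.0080 to 0.12, so that bias stays open as part of their rise.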
